A study of Arabidopsis thaliana with 44 samples.

How the data were processed

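The series holds RNA sequencing of whole Arabidopsis seedlings grown in the dark for 14 days, in orbit or in matched ground hardware run with a 2-day delay, and fixed in RNAlater. Seeds, 70 to 80 per 60 mm plate with 0.5 percent sucrose, were held in 22 fixation units in 4 canisters per the labels. The 5 genotypes were WT, bzip28, bzip60, bzip28bzip60 and ire1aire1b, with 4 libraries in each of the 10 groups. Of the 44 labelled samples 4 have no column in the table. The labels state that these served only for first quality controls. All 40 columns were used, and each was assigned to its group by its column name and sample title.

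The authors deposited 1 table of 34133 loci in FPKM, fragments scaled by transcript length and by the mapped fragments of the library. The submitters' processing notes name FastQC 0.11.5 and cutadapt 1.8.1 for the reads, Bowtie2 2.2.4 and TopHat2 2.0.14 for alignment to TAIR10, and Cufflinks 1.3.0 for the FPKM values. The libraries were made with a stranded messenger RNA kit per the labels. No read counts were used here, so the depth per library is unknown. The precision of a value was taken from the spread of libraries within groups, pooled over the 10 groups. The labels name no repeat of the flight run or of the ground run. The p-values for flight against ground therefore do not cover differences between runs. Listed zeros were kept as 0, and 263 of 13827 genes with a mean FPKM of at least 5 were listed at 0 in 1 or more libraries. Gene names came from the reference annotation, which named 31510 of the loci. It is a later release than the authors' annotation, so it was used only for names and gene order.

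Values were taken to log2(FPKM + 1), and the 19186 genes with a mean FPKM of at least 1 over the 40 libraries were tested. One linear model with a mean for each group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, 30 residual degrees of freedom). It gave 18 comparisons: flight against ground in each of the 5 genotypes and their mean, each of the 4 mutants against WT on the ground and in flight, and the flight response of each mutant minus that of WT. P-values were adjusted within a comparison by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. The 4 mutants share the WT libraries, so their comparisons with WT are not independent. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

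The main values are the FPKM as deposited. Because total FPKM differed between the conditions, every comparison was also run after median-ratio rescaling over the 14104 genes above 1 FPKM in all libraries. That alternative was named before the data were examined, as were the genotype and condition groups, the filter, the pseudocount, the gene lists and the rule by which genes are named. Named genes had a mean of at least 5 FPKM in 1 of the compared groups and, in comparisons of 2 groups, values that did not overlap. For the mean every genotype had to change in the same direction, and the interactions had no such rule. The largest changes were taken, 10 up and 10 down for WT flight and the mean. Each mutant in flight against ground and against WT on the ground had 5 and 5, and the other comparisons 3 and 3. List members, up to 4 per list, were chosen without the FPKM and overlap rules, by the largest change among those called. The 4 disrupted genes were named in every comparison. Rescaling assumes that most genes do not change. It was tested on simulated data in which 200 of 19186 genes were changed, so a case with as many changed genes as were called here was not tested. Of 100 genes simulated with a log2 change of 1 and 100 of 2 in WT flight, 89 and 97 were recovered after rescaling with 19 false calls, and 62 and 97 with 17015 false calls on the libraries' own scale. For bzip28 against WT on the ground 93 and 98 were recovered after rescaling with 8 false calls, and 71 and 96 with 2 on the own scale. Swapped libraries were first tested on 4 to 10 genes per genotype that separate bzip28 from it 4-fold in flight. On the ground these kept their side for 90 percent against WT but for as few as 50 percent against bzip60 as deposited, and that test was not used for a decision.

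Gene lists were tested with camera in limma, with its preset correlation of 0.01 and with the correlation estimated from the residuals. Camera compares a list with all other tested genes, so its p-value is not a test of the members against no change. There were 28 lists of known genes written before the data were examined and 2 of all organelle genes, 30 in all. They named 464 genes outside the organelle lists, of which 463 were in the table and 370 were tested. Camera p-values were adjusted over the 30 lists of a comparison. List counts are also given after adjustment over the members of the list alone. Correlations were tested by permutation, 100000 for 10 or more libraries and all orders for fewer.

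Alternatives named before the data were examined were a pseudocount of 0.1, no filter (28434 genes), a filter at a mean of 5 FPKM (13827 genes), rescaling, lane as a covariate, lanes 2 and 4 alone, the letter in the library name as a covariate, a replicate block, a fit to the compared groups alone and omission of each library in turn. Lane and letter were read from the sample titles. Lane 1 held 11 flight and no ground libraries, lane 2 held 4 and 6, lane 3 held 9 ground libraries and lane 4 held 5 and 5. Each alternative on rescaled values, and the omission of the 2 ground libraries with the lowest scale factors, were added after the data were examined. Replicate numbers were tested for pairing by correlating the residuals of libraries with the same number. In 0 of 5 flight and ground comparisons and 0 of 8 mutant and WT comparisons did every same-number pair exceed 0.1. The main model therefore has no pairs. By letter and digit in the titles, WT libraries 3 and 4 and bzip28bzip60 library 4 do not match between flight and ground. Pairing by title was not tested, and the replicate block uses the same numbers. On the ground 3, 4, 1 and 3 libraries of bzip28, bzip60, bzip28bzip60 and ire1aire1b correlated best with the same-number WT library as deposited. In flight these were 1, 2, 1 and 1. Labels were also regrouped in all 35 ways of dividing 8 libraries into 4 and 4, or 100 draws for the mean and the interactions.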

Results

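Dark-grown Arabidopsis seedlings of 5 genotypes were compared after 14 days in orbit and in matched ground hardware: WT (Col-0), bzip28-2, bzip60-2, bzip28-2 bzip60-1 and ire1a-4 ire1b-2, below bzip28, bzip60, bzip28bzip60 and ire1aire1b. bZIP28, bZIP60 and the IRE1 kinases relay stress from the endoplasmic reticulum to the nucleus, and IRE1 splices the bZIP60 transcript. Each of the 10 groups held 4 libraries of whole seedlings, and every mean ± SD below is FPKM over n = 4 libraries of a group unless another n is given. Each log2 change is a difference of log2(FPKM + 1) of the deposited values, finite also where a library is listed at 0, followed in brackets by that of the rescaled values described next. Counts and p-values of gene lists likewise give the deposited values first and the rescaled ones second. Camera p-values set a list against all other tested genes. Where most genes are higher, a list with many higher members can still lie below the others. "Rose" and "fell" are kept for genes past an adjusted p of 0.05 (limma, Benjamini-Hochberg) in the same direction on both scales.

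One locus took a large share of the deposited FPKM. AT2G01021, a short open reading frame inside the ribosomal RNA genes, was listed at 239748 ± 162551 FPKM in flight and 1381395 ± 478276 on the ground (n = 20 libraries each). It made up 22.5 ± 12.9 percent of all FPKM in the flight libraries and 72.5 ± 14.1 percent in the ground libraries. The median FPKM of the tested genes was 13.3 ± 1.04 in flight and 7.26 ± 2.05 on the ground, and 24324 ± 254 and 22681 ± 739 loci were listed above 0. The bzip60 ground libraries stood closest to flight, with a log2 scale factor of 0.14 ± 0.16 against -0.39 ± 0.41 for all ground libraries and 0.40 ± 0.11 for all flight libraries. Among ground libraries the FPKM of AT2G01021 and the log2 scale factor had r = -0.826 (permutation test, n = 20, p = 1e-05, adjusted over 5 relations p = 2.5e-05, rank correlation -0.82, and -0.736 without the 2 libraries farthest out). Among flight libraries r was -0.937 (n = 20, the same adjusted p, rank correlation -0.964, and -0.927 without the 2 farthest). By permutation tests, exact for fewer than 10 libraries, r within single sequencing lanes was -0.947 for lane 1 (flight, n = 11), -0.923 for lane 3 (ground, n = 9) and -0.953 for lane 2 (ground, n = 6, where the rank correlation of -0.771 had p = 0.1). Without the 2 farthest libraries these were -0.929, -0.813 and -0.481. As deposited, the median tested gene was 0.88 higher in flight on the log2 scale in WT, 0.97 in bzip28, 0.33 in bzip60, 0.71 in bzip28bzip60 and 0.92 in ire1aire1b, and 0.08 to 0.10 higher after median-ratio rescaling. Every count is therefore given on both scales.

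**Figure D1:**
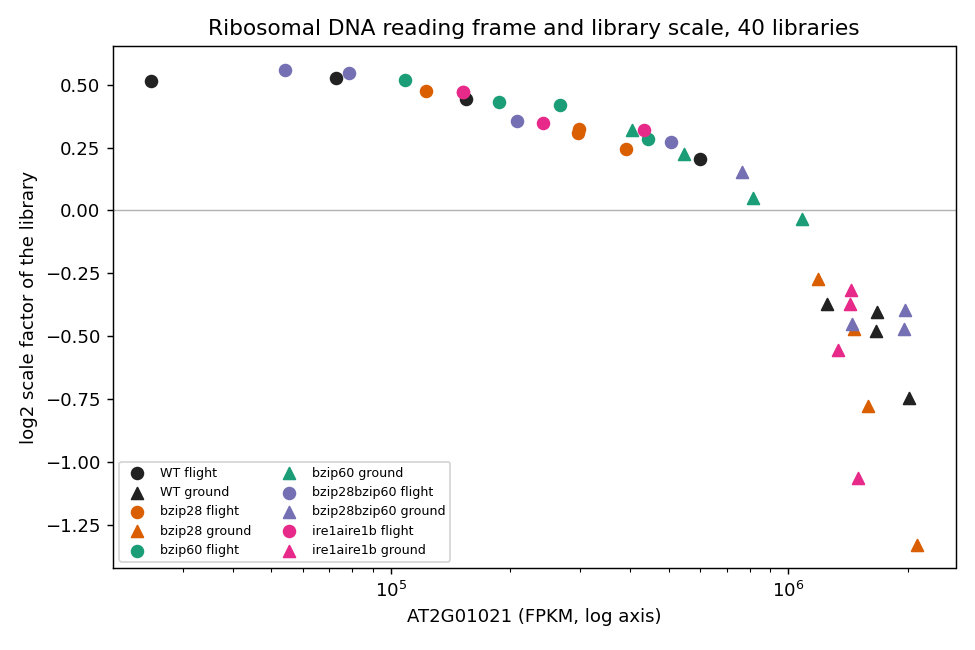
Deposited FPKM of the ribosomal RNA locus AT2G01021 and the log2 scale factor of each of the 40 libraries, flight against ground: the mean scale factor was 0.40 in flight and -0.39 on the ground. Ground libraries with more AT2G01021 had lower scale factors (r = -0.826).

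The transcripts of the 4 disrupted genes were read first. IRE1A stood at 36.4 ± 2.58 in WT flight and 30.3 ± 3.3 in WT ground libraries, against 1.35 ± 0.139 and 1.05 ± 0.381 in ire1aire1b, a log2 difference of -3.99 (-3.8) in flight and -3.95 (-4.14) on the ground. IRE1B was lowered less in ire1aire1b, -1.02 (-1.05) on the ground and -0.74 (-0.69) in flight, where the deposited values missed the test (limma adjusted p = 0.0763 as deposited, 1.28e-04 rescaled). bZIP60 was at 15.4 ± 1.46 and 13.5 ± 1.48 in bzip60 against 36.6 ± 3.2 and 48.9 ± 5.33 in WT, -1.2 (-1.17) in flight and -1.78 (-2.4) on the ground, and -1.16 (-1.15) and -2.3 (-2.52) in bzip28bzip60. bZIP28 fell in bzip28bzip60 to 5.22 ± 0.295 in flight and 2.57 ± 0.69 on the ground, -1.94 (-1.89) and -2.64 (-2.91). In the libraries labelled bzip28 the same transcript was higher than in WT: 108 ± 16.9 against 22.9 ± 1.57 in flight, 2.18 (2.25), and 43.7 ± 16.5 against 20.9 ± 1.41 on the ground, 0.95 (1.17). The 4 flight libraries of bzip28 all lay above every flight library of another genotype, by a factor of at least 3.44 as deposited and 4.03 rescaled. On the ground that factor was 0.79 as deposited and 1.59 rescaled. FPKM counts reads over the whole gene, so a partial transcript and a full one were not told apart.

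**Figure D2:**
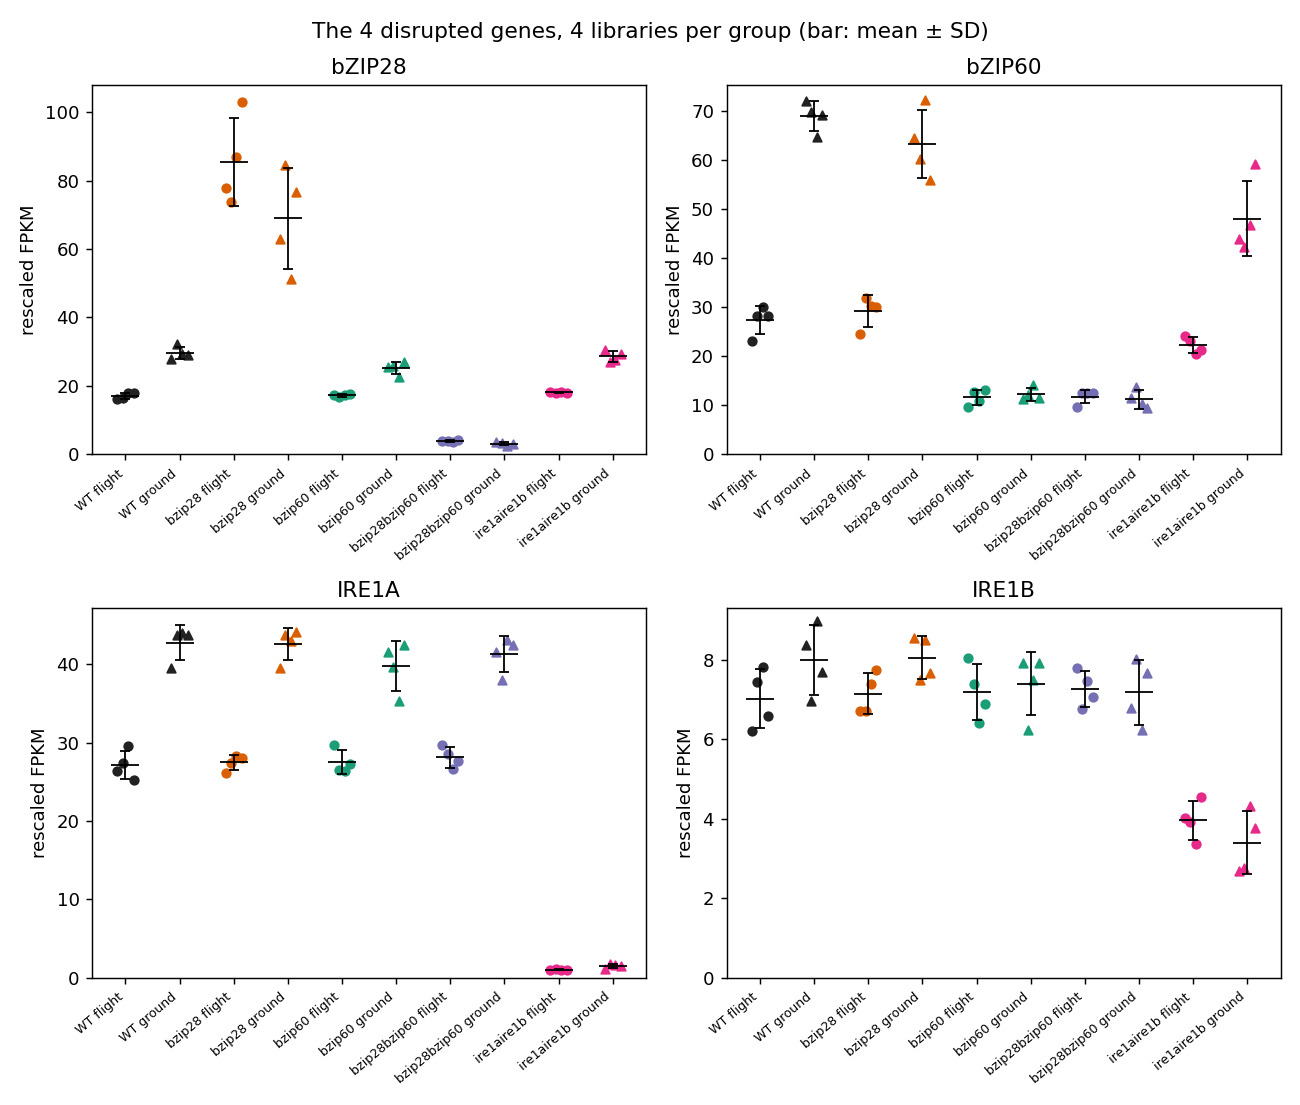
Rescaled FPKM of bZIP28, bZIP60, IRE1A and IRE1B in each library by genotype and condition, with mean ± SD (n = 4). bZIP28 was at 85.4 ± 12.9 in bzip28 and 17.1 ± 0.998 in WT flight libraries, whereas the other targets were lower in their own mutants.

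In WT several of the largest flight rises were at neighbouring loci. AT4G22490 was at 336 ± 164 in flight and 1.03 ± 0.512 on the ground, 7.28 (6.6). Beside it AT4G22485, AT4G22513, AT4G22517 and AT4G22520 were at 59.6 to 284, 137 to 395, 187 to 612 and 86.2 to 318 in the 4 flight libraries. These 4 were listed at 0 in 1, 3, 1 and 1 of the 4 ground libraries and reached at most 0.0821, 0.116, 0.312 and 0.508 there. A second pair of neighbours, AT3G05730 and AT3G05727, went the same way: AT3G05730 was at 179 ± 17.2 against 0.429 ± 0.315, 7.0 (6.42), and AT3G05727 at 311 to 794 in flight, with 2 ground libraries listed at 0 and the highest at 1.92. AT3G16670 was at 108 to 205 in flight, with 3 ground libraries listed at 0, and AT2G41082 at 41.3 to 212, with all 4 listed at 0. The plastid gene ATCG00410 ranged from 96.5 to 871 in flight, with 3 ground libraries listed at 0 and the other at 56.5. Its log2 change of 6.62 (6.10) had a standard error of 2.11 (2.24). For the plastid genes named below among the largest rises of the mutants, the deposited standard errors were 1.42 to 1.78. That of AT3G16670 in WT was 0.239. ESM1, the epithiospecifier modifier, was at 74.4 ± 18.4 in flight and 0.163 ± 0.0499 on the ground.

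Among the WT genes that fell most in flight, the glyoxalase GLYI7 was at 8.95 ± 3.04 in flight and 110.1 ± 25.5 on the ground, -3.52 (-4.39), and the nitrilase NIT2 at 17 ± 6.34 and 147 ± 45.5, -3.03 (-3.92). The tonoplast intrinsic protein BETA-TIP, found in seed storage vacuoles, fell from 41.6 ± 7.0 to 3.78 ± 1.14, -3.17 (-3.99), and the blue-copper-binding protein BCB from 134 ± 34.8 to 17.1 ± 4.43, -2.88 (-3.78). Isocitrate lyase ICL, of the glyoxylate cycle, was at 37.8 ± 3.42 against 213 ± 30.1. AT4G33467 -2.73 (-3.59) and AT4G25580 -2.68 (-3.51) also fell, as did M10, AT1G43675.1 and AT1G03106, which were listed at 0 in 2, 1 and 1 of the flight libraries and were at 6.14 to 12.6, 2.79 to 18.6 and 6.31 to 9.34 on the ground. AT2G01021 itself was -3.83 (-4.76). By limma with Benjamini-Hochberg adjustment, 14934 genes were higher and 592 lower in WT flight as deposited, and 6818 and 4772 after rescaling, of 19186 tested. On both scales 6818 were higher and 592 lower, and 1616 were called higher as deposited and lower after rescaling.

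Genes that darkness and sugar shortage induce were lower in WT flight. DIN2 fell from 105 ± 28 to 19.6 ± 6.66, -2.38 (-3.27), with BCAT2 -1.83 (-2.74), DIN6 -1.45 (-2.37) and DIN9 -1.23 (-1.95). Of the starvation list the median was -0.75 (-1.66), 0 higher and 13 lower of 20 (0 and 12 adjusted over the list alone), 0 and 20 rescaled (0 and 20). For that list camera adjusted p = 2.17e-22 and 7.87e-17 rescaled (p = 0.162 and 0.0409 with estimated correlation). Senescence genes followed: NAP fell from 64.4 ± 12.8 to 13.1 ± 5.8, -2.28 (-3.16), with WRKY6 -0.94 (-1.76) and NAC092 -0.63 (-1.53), whereas SAG101 was higher, 1.38 (0.53). The senescence list had 1 higher and 4 lower of 7 (1 and 5 adjusted over the list alone), 1 and 6 rescaled (1 and 6), and camera adjusted p = 1.42e-06 and 2.87e-04 rescaled (p = 0.235 and 0.0497 with estimated correlation).

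Genes of cell wall loosening rose in WT flight. XTH19 went from 1.28 ± 0.783 to 85.3 ± 19.3, 5.27 (4.55), and EXPA11 4.25 (3.55), XTH4 4.2 (3.3) and EXPA1 3.49 (2.62) also rose. The list of expansins and xyloglucan endotransglucosylases had a median of 2.35 (1.59) and 20 higher and 1 lower of 22 (20 and 1 adjusted over the list alone), 17 and 3 rescaled (17 and 3). For it camera adjusted p = 8.91e-04 and 9.75e-05 rescaled (p = 0.619 and 0.0497 with estimated correlation). Epidermal genes rose too: PDF1 from 4.77 ± 1.63 to 224 ± 82.5, 5.26 (4.42), and LTP1 4.82 (3.96). The shoot epidermis and cuticle list had 7 higher and 0 lower of 8 (7 and 0 adjusted over the list alone), 6 and 1 rescaled (6 and 1), and camera adjusted p = 0.0282 and 0.00856 rescaled (p = 0.704 and 0.479 with estimated correlation).

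Nuclear photosynthesis genes rose in WT flight although all seedlings were kept dark. LHCB1.3 was at 388 ± 30.1 in flight and 34.7 ± 14.4 on the ground, and GAPB 3.78 (2.97), LHCB5 3.69 (2.81) and PSAK 3.61 (2.76) rose. RBCS1B was at 65.4 to 92.2 in flight and at 0 to 0.386 on the ground, 1 library being listed at 0. The list had a median of 2.64 (1.73) and 35 higher and 0 lower of 35 (35 and 0 adjusted over the list alone), 33 and 0 rescaled (33 and 0). For it camera adjusted p = 1.17e-09 and 3.98e-11 rescaled (p = 0.619 and 0.347 with estimated correlation). PIL1, which shade induces, rose from 4.53 ± 1.68 to 82.9 ± 11.9, 3.96 (3.12), and the light signalling list had 8 higher and 1 lower of 9 (8 and 1 adjusted over the list alone), 3 and 1 rescaled (3 and 1), with camera adjusted p = 0.677 and 0.578 rescaled (p = 0.928 and 0.835 with estimated correlation).

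After rescaling, plastid genes summed to 46575 ± 14182 FPKM in flight and 23239 ± 6587 on the ground, and mitochondrial genes to 1741 ± 655 and 7093 ± 3533 (n = 20 libraries each). In WT the plastid-encoded list had 82 higher and 0 lower of 94 (84 and 0 adjusted over the list alone), 60 and 0 rescaled (60 and 0), and camera adjusted p = 0.179 and 1.62e-04 rescaled (p = 0.928 and 0.64 with estimated correlation). The mitochondrion-encoded list had 11 higher and 10 lower of 61 (8 and 9 adjusted over the list alone), 1 and 28 rescaled (1 and 21), and camera adjusted p = 7.01e-18 and 0.00104 rescaled (p = 0.162 and 0.557 with estimated correlation). Its ATMG00030 fell, -2.55 (-3.47). The mitochondrial sum also rose with AT2G01021 among the ground libraries (r = 0.719, n = 20, permutation test adjusted over 4 relations p = 0.00082, rank correlation 0.719, and 0.63 without the 2 farthest) and the flight libraries (r = 0.883, n = 20, p = 4e-05, rank correlation 0.899, and 0.859). For the plastid sum r was 0.236 on the ground (n = 20, p = 0.32, rank correlation 0.188, and 0.132) and 0.591 in flight (n = 20, p = 0.0085, rank correlation 0.738, and 0.709). These 4 relations were looked at after the sums were known.

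Cytosolic ribosomal protein genes rose in WT flight, with RPL23AA at 2.23 (1.32). Their list had a median of 1.57 (0.65) and 19 higher and 0 lower of 19 (19 and 0 adjusted over the list alone), 18 and 0 rescaled (18 and 0), and camera adjusted p = 1.19e-04 and 3.02e-07 rescaled (p = 0.704 and 0.218 with estimated correlation). Of the hypoxia genes HB1 rose from 54.8 ± 21.8 to 348 ± 88.2, 2.72 (1.81), with ACO1 3.69 (2.94), SAD6 3.33 (2.6) and PDC1 2.33 (1.58). The hypoxia list had 15 higher and 0 lower of 15 (15 and 0 adjusted over the list alone), 10 and 0 rescaled (10 and 0), and camera adjusted p = 0.0282 and 0.0485 rescaled (p = 0.704 and 0.64 with estimated correlation). FSD1, an iron superoxide dismutase, rose from 132 ± 20.5 to 2209 ± 187, 4.07 (3.15), and UPOX 2.12 (1.33), whereas ZAT12 fell, -1.38 (-2.23). The oxidative stress list had 8 higher and 5 lower of 19 (8 and 4 adjusted over the list alone), 4 and 11 rescaled (4 and 11), and camera adjusted p = 0.00214 and 0.00856 rescaled (p = 0.704 and 0.233 with estimated correlation). RD22 rose, 3.78 (2.96), while NCED3 -1.09 (-1.91), RD29B -0.96 (-1.37) and RAB18 -0.81 (-1.3) fell. The cold, drought and abscisic acid list had 1 higher and 3 lower of 11 (1 and 2 adjusted over the list alone), 1 and 9 rescaled (1 and 10), and camera adjusted p = 7.2e-07 and 0.0277 rescaled (p = 0.261 and 0.551 with estimated correlation). DREB2A fell, -1.01 (-1.92), and HSFA3 rose, 1.3 (0.55). The cytosolic heat shock list had 8 higher and 1 lower of 23 (7 and 1 adjusted over the list alone), 3 and 12 rescaled (3 and 12). For it camera adjusted p = 1.59e-04 and 0.0267 rescaled (p = 0.675 and 0.58 with estimated correlation). As deposited 14934 of 19186 tested genes were higher in WT flight, a larger share than in the oxidative stress and heat shock lists. The deposited camera p-values of these lists therefore do not stand for a rise.

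Of the stress genes of the endoplasmic reticulum bZIP60 fell in WT flight, -0.4 (-1.3) (limma adjusted p = 0.0382 as deposited, 8.52e-12 rescaled), and bZIP28 0.12 (-0.76), IRE1A 0.26 (-0.64) and IRE1B 0.64 (-0.17) changed direction with the scale. BAG7 0.89 (-0.02) lost its call after rescaling. The list of sensors and transducers had 6 higher and 1 lower of 12 (6 and 0 adjusted over the list alone), 0 and 8 rescaled (0 and 8). For it camera adjusted p = 0.034 and 0.00103 rescaled (p = 0.704 and 0.0416 with estimated correlation). As deposited its share higher was below that of all tested genes in WT flight (14934 of 19186). Among chaperones of the same compartment CRT1A rose, 1.59 (0.68), and HSP90.7 rose, 1.59 (0.68). The protein folding list had 20 higher and 0 lower of 22 (20 and 0 adjusted over the list alone), 10 and 2 rescaled (10 and 2), and camera adjusted p = 0.484 and 0.446 rescaled (p = 0.928 and 0.737 with estimated correlation). DAD1 1.25 (0.34) passed only as deposited, and the list of degradation and translocation had 7 higher and 0 lower of 9 (7 and 0 adjusted over the list alone), 0 and 4 rescaled (1 and 5), with camera adjusted p = 0.484 and 0.0543 rescaled (p = 0.928 and 0.236 with estimated correlation).

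**Figure D3:**
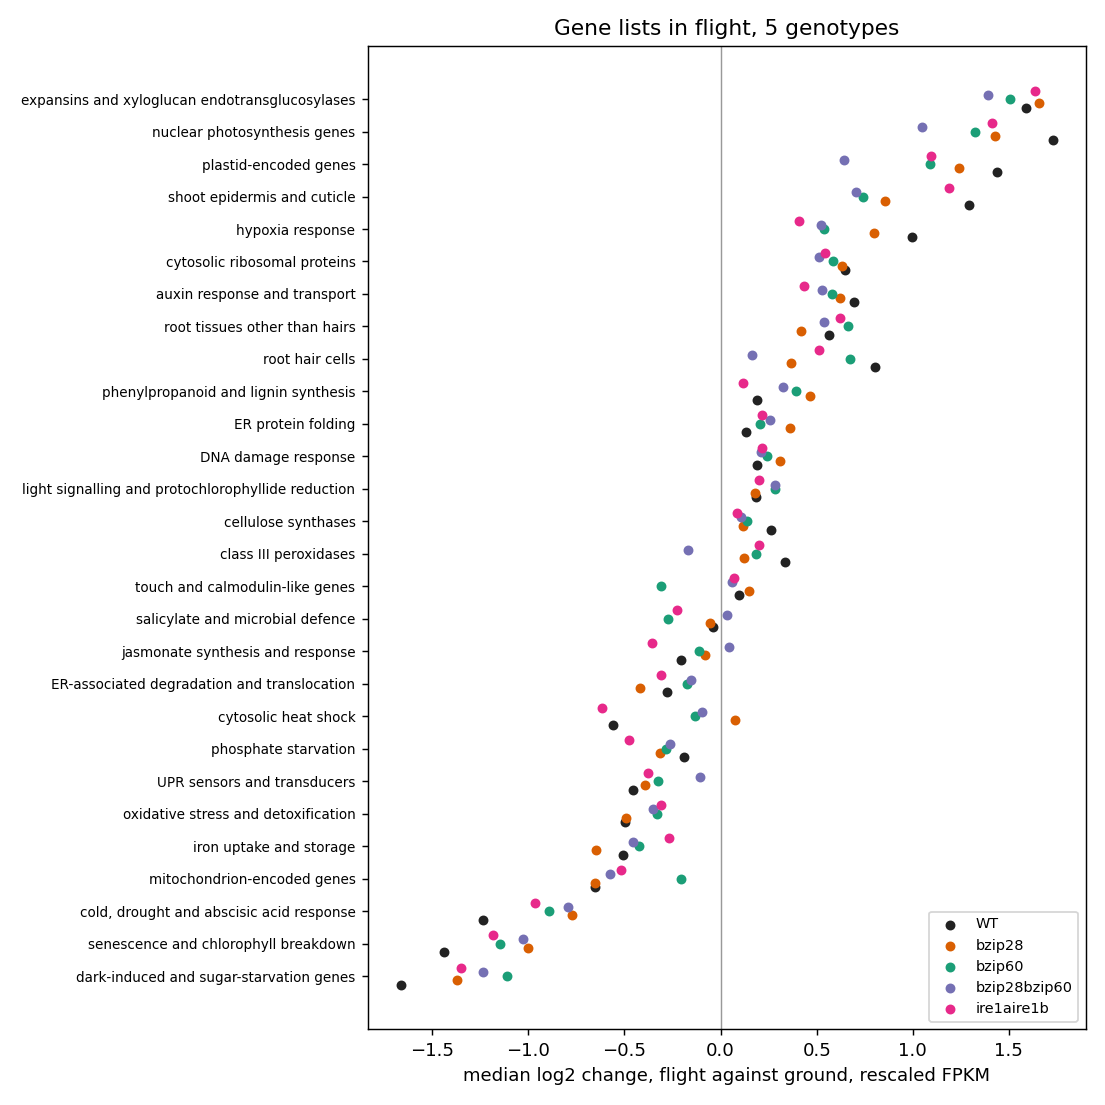
Median rescaled log2 change in flight of each gene list with at least 4 measured genes, by genotype. In WT the starvation list was at -1.66 (-0.75 as deposited) and the UPR sensors and transducers at -0.46, against 0.42 as deposited, so that list changed direction with the scale.

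In WT flight the auxin genes SAUR19 3.15 (2.6) and IAA3 2.56 (1.75) rose, and so did the flavonoid genes CHS 2.88 (2.41) and CHI 2.11 (1.61). The auxin list had 12 higher and 0 lower of 15 (12 and 0 adjusted over the list alone), 10 and 3 rescaled (10 and 3), with camera adjusted p = 0.162 and 0.0538 rescaled (p = 0.851 and 0.551 with estimated correlation), and the flavonoid list, of which only 2 genes were measured, 2 higher and 0 lower of 2 (2 and 0 adjusted over the list alone), 2 and 0 rescaled (2 and 0), with camera adjusted p = 0.15 and 0.0713 rescaled (p = 0.619 and 0.315 with estimated correlation). The salicylate enzyme gene SID2 4.08 (3.39) and PR5 2.62 (2.27) rose and NHL10 -1.38 (-2.06) fell, in a list with 8 higher and 1 lower of 14 (8 and 1 adjusted over the list alone), 3 and 6 rescaled (3 and 6), with camera adjusted p = 0.0724 and 0.578 rescaled (p = 0.73 and 0.835 with estimated correlation). CYP94B3 fell, -1.31 (-2.12), in the jasmonate list, 10 higher and 1 lower of 16 (10 and 1 adjusted over the list alone), 0 and 5 rescaled (0 and 4). For that list camera adjusted p = 0.0234 and 0.0485 rescaled (p = 0.704 and 0.551 with estimated correlation). Its deposited share higher was also below that of all tested genes in WT flight. The peroxidases PRX37 2.82 (2.01) and PRX33 2.74 (2.3) rose, in a list with 11 higher and 1 lower of 17 (11 and 1 adjusted over the list alone), 7 and 4 rescaled (8 and 5), with camera adjusted p = 0.347 and 0.848 rescaled (p = 0.928 and 0.921 with estimated correlation).

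In bzip28 flight BETA-TIP -2.76 (-3.73), GLYI7 -2.67 (-3.68), ICL -2.67 (-3.7) and AT1G03106 fell, and XTH and expansin genes rose. AT4G22517, AT4G22513, AT3G05727, AT3G16670 and the plastid gene ATCG00390 were among the highest in flight, AT3G05727 at 7.65 (7.0). By limma with Benjamini-Hochberg adjustment 15777 genes were higher and 361 lower as deposited and 6740 and 4650 after rescaling, with 6740 and 361 on both. Of the rest 2184 were higher as deposited but lower rescaled. The starvation list had 2 higher and 6 lower of 20 (1 and 6 adjusted over the list alone), 0 and 20 rescaled (0 and 20), and camera adjusted p = 1.12e-17 and 4.94e-15 rescaled (p = 0.311 and 0.0342 with estimated correlation). The expansin list had 21 higher and 1 lower of 22 (21 and 1 adjusted over the list alone), 18 and 2 rescaled (18 and 2), and camera adjusted p = 8.37e-05 and 2.18e-06 rescaled (p = 0.53 and 0.0342 with estimated correlation).

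In bzip60 more genes fell in flight as deposited than in any other genotype, on a ground scale closer to flight. The germin-like gene GLP9 -3.25 (-3.45), SIS -3.1 (-3.36), AT1G58320 -3.22 (-3.31), AT3G55790 -3.11 (-3.15) and AT4G19829 -3.44 (-3.46) fell most. AT4G22517, AT4G22513, AT3G16670, AT3G05727 and ATCG00320 rose most, AT3G05727 by 6.85 (6.55). As deposited 7790 genes were higher and 1530 lower, and 6371 and 4365 after rescaling, with 6363 and 1528 on both and no gene changing direction. The starvation list had 0 higher and 17 lower of 20 (0 and 17 adjusted over the list alone), 0 and 20 rescaled (0 and 20), and camera adjusted p = 4.98e-14 and 1.14e-14 rescaled (p = 0.428 and 0.0381 with estimated correlation). The expansin list had 18 higher and 1 lower of 22 (18 and 1 adjusted over the list alone), 17 and 2 rescaled (17 and 2), and camera adjusted p = 4.69e-07 and 2.79e-06 rescaled (p = 0.428 and 0.0381 with estimated correlation).

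The bzip28bzip60 seedlings lowered BETA-TIP -2.69 (-3.32), ICL -2.6 (-3.31) and AT4G25580 -2.29 (-2.92) in flight, with AT1G03106 and AT2G01021. AT4G22517, AT4G22513, AT4G22520, AT3G05727 and the plastid gene ATCG00260 rose most, AT3G05727 by 7.23 (6.59). As deposited 13654 genes were higher and 507 lower, and 6260 and 4312 after rescaling, with 6260 and 507 on both and 605 changing direction. The starvation list had 0 higher and 11 lower of 20 (0 and 8 adjusted over the list alone), 0 and 20 rescaled (0 and 20), and camera adjusted p = 1.71e-17 and 2.25e-15 rescaled (p = 0.309 and 0.031 with estimated correlation). The expansin list had 20 higher and 0 lower of 22 (20 and 0 adjusted over the list alone), 18 and 2 rescaled (18 and 2), and camera adjusted p = 8.1e-06 and 2.12e-06 rescaled (p = 0.425 and 0.031 with estimated correlation).

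In ire1aire1b the flight falls were led by BETA-TIP -2.95 (-3.82), CYCP2;1 -2.68 (-3.42), GLYI7 -2.51 (-3.45) and SIS -2.42 (-3.39). AT3G05727 8.85 (8.18) and AT4G22490 7.04 (6.3) rose, beside AT4G22517, AT4G22513 and ATCG00260. As deposited 15468 genes were higher and 416 lower, and 6555 and 4588 after rescaling, with 6555 and 415 on both and 1878 changing direction. The starvation list had 1 higher and 8 lower of 20 (0 and 7 adjusted over the list alone), 0 and 20 rescaled (0 and 20), and camera adjusted p = 8.5e-19 and 9.65e-16 rescaled (p = 0.237 and 0.0315 with estimated correlation). The expansin list had 21 higher and 0 lower of 22 (21 and 1 adjusted over the list alone), 18 and 2 rescaled (18 and 2), and camera adjusted p = 6.58e-05 and 4.88e-06 rescaled (p = 0.591 and 0.0315 with estimated correlation). The senescence list had 2 higher and 2 lower of 7 (2 and 2 adjusted over the list alone), 0 and 6 rescaled (0 and 6), and camera adjusted p = 1.49e-06 and 2.07e-04 rescaled (p = 0.237 and 0.0401 with estimated correlation).

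Averaged over the 5 genotypes the loci AT4G22485, AT4G22490, AT4G22513, AT4G22517 and AT4G22520, AT3G05727, AT3G05730, AT3G16670, AT1G23130 and ESM1 5.65 (5.18) rose most. BETA-TIP -2.9 (-3.59), GLYI7 -2.68 (-3.42), ICL -2.53 (-3.31), NIT2 -2.44 (-3.21), SIS -2.31 (-3.09) and the cyclin gene CYCP2;1 -2.3 (-2.91) fell most, with AT1G03106, AT1G58320, AT3G55790 and AT2G01021. In this mean 16223 genes were higher and 1069 lower as deposited and 8974 and 6392 after rescaling, with 8974 and 1068 on both and 3729 changing direction. All 5 genotypes shared 7685 higher and 227 lower genes as deposited, and 4636 and 3081 after rescaling. WT shared 5584 to 5768 higher and 3738 to 3938 lower genes with each mutant after rescaling, where independent lists would share 2225 to 2395 and 1073 to 1157, and 2 to 10 genes were called in opposite directions. Over the tested genes the rescaled log2 changes of WT and of a mutant had r = 0.902 to 0.919. The least-squares slopes of mutant on WT were 0.85 for bzip28, 0.80 for bzip60, 0.77 for bzip28bzip60 and 0.86 for ire1aire1b. Noise in the WT changes pulls such slopes below 1, so they do not by themselves show a weaker response in the mutants. In the mean the starvation list had 1 higher and 16 lower of 20 (1 and 16 adjusted over the list alone), 0 and 20 rescaled (0 and 20), and camera adjusted p = 2.19e-24 and 8.28e-13 rescaled (p = 0.148 and 0.0916 with estimated correlation). The protein folding list of the endoplasmic reticulum had 22 higher and 0 lower of 22 (22 and 0 adjusted over the list alone), 15 and 3 rescaled (15 and 3), and camera adjusted p = 0.107 and 0.0364 rescaled (p = 0.802 and 0.465 with estimated correlation).

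On the ground bzip28 differed from WT at 135 genes as deposited and 641 after rescaling. HEI10 -3.17 (-3.24) and its overlapping neighbour MRD1 -2.99 (-3.41) were lower, as were AT4G04223 -2.31 (-2.36), AT5G03090 -2.08 (-2.4) and AT2G38390 -1.99 (-1.92), and AT2G34590 1.67 (1.89) was higher. The folding genes PDIL2-2 -0.93 (-0.86), ERDJ3A -0.78 (-0.77) and BIP2 -0.72 (-0.54) were lower, with 0 higher and 3 lower of 22 (0 and 18 adjusted over the list alone), 0 and 11 rescaled (0 and 17), and camera adjusted p = 3.31e-12 and 3.03e-18 rescaled (p = 0.367 and 2.93e-04 with estimated correlation). SMR7 -1.82 (-1.78), XRI1 -1.17 (-1.11), TSO2 -1.08 (-0.92) and PARP2 -0.92 (-0.97) of the DNA damage list were lower, with 0 higher and 6 lower of 16 (0 and 12 adjusted over the list alone), 0 and 7 rescaled (1 and 12), and camera adjusted p = 1.05e-10 and 1.98e-10 rescaled (p = 0.235 and 3.95e-05 with estimated correlation). HB1 -1.76 (-1.58) and ADH1 -1.19 (-1.01) were lower in the hypoxia list, and CCOAOMT1 -1.03 (-0.83) and PAL1 -0.92 (-0.72) in the phenylpropanoid list, which had 0 higher and 3 lower of 14 (0 and 11 adjusted over the list alone), 0 and 8 rescaled (0 and 9), and camera adjusted p = 2.31e-08 and 3.84e-11 rescaled (p = 0.367 and 0.0279 with estimated correlation). By limma with Benjamini-Hochberg adjustment 4 genes were higher and 131 lower as deposited, 218 and 423 after rescaling, and 4 and 130 on both. The count was 59 without bzip28 ground 1 and 531 without bzip28 ground 4.

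The bzip60 ground libraries lay above WT at most genes as deposited, with a median of 0.55 that became 0.01 after rescaling. AT2G01021 made up 50.8 ± 13.5 percent of their FPKM against 79.5 ± 4.5 in WT ground libraries. Their rescaled mitochondrial sum was 3193 ± 1145 against 7650 ± 1949. Whether the differences below follow from this was not tested. AT2G34590 2.36 (1.74), AT3G55790 2.75 (2.35) and GASA4 2.28 (1.65) were higher, and HEI10 -2.96 (-3.52), MRD1 -2.93 (-3.4), AT5G03090 -1.56 (-2.05) and BCB -1.17 (-1.8) lower. AT4G19829 3.38 (3.06) and MIR834 2.52 (2.14) were higher as deposited only. ERDJ3A -0.7 (-1.16) was lower in the protein folding list, which had 10 higher and 1 lower of 22 (9 and 1 adjusted over the list alone), 0 and 9 rescaled (0 and 12), and camera adjusted p = 0.00315 and 6.65e-10 rescaled (p = 0.623 and 0.00773 with estimated correlation), so its direction turned with the scale. The photosynthesis genes LHCB1.3 2.05 (1.42), PSAG 1.73 (1.1) and LHCB5 1.7 (1.1) were higher, in a list with 34 higher and 0 lower of 35 (34 and 0 adjusted over the list alone), 8 and 0 rescaled (12 and 0), and camera adjusted p = 2.79e-06 and 5.96e-10 rescaled (p = 0.607 and 0.338 with estimated correlation). The DNA damage list, with PARP2 -0.48 (-0.93), had 4 higher and 2 lower of 16 (4 and 2 adjusted over the list alone), 0 and 8 rescaled (2 and 10), and camera adjusted p = 5.6e-11 and 1.84e-07 rescaled (p = 0.0964 and 7.63e-04 with estimated correlation). The starvation list had 5 higher and 0 lower of 20 (4 and 0 adjusted over the list alone), 0 and 9 rescaled (0 and 13), and camera adjusted p = 2.31e-05 and 1.21e-11 rescaled (p = 0.607 and 0.0382 with estimated correlation). As deposited 13395 genes were higher and 48 lower, after rescaling 433 and 453, and on both 433 and 44.

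The bzip28bzip60 ground libraries had more AT5G35375 3.17 (3.26), AT2G34590 1.92 (1.73), GASA4 1.73 (1.52), LHCB1.3 1.71 (1.51) and AT2G10940 1.66 (1.48) than WT, and less HEI10 -3.05 (-3.38), MRD1 -2.83 (-3.22) and AT5G03090 -1.83 (-2.15). ERDJ3A -1.1 (-1.37) and PDIL2-2 -0.61 (-0.83) were lower, in a protein folding list with 0 higher and 2 lower of 22 (0 and 4 adjusted over the list alone), 0 and 10 rescaled (0 and 14), and camera adjusted p = 4.58e-12 and 3.09e-20 rescaled (p = 0.354 and 9.79e-05 with estimated correlation). The photosynthesis list had 8 higher and 0 lower of 35 (25 and 0 adjusted over the list alone), 8 and 0 rescaled (25 and 0), and camera adjusted p = 8.76e-19 and 4.19e-17 rescaled (p = 0.343 and 0.15 with estimated correlation). The DNA damage list had 0 higher and 0 lower of 16 (0 and 5 adjusted over the list alone), 0 and 7 rescaled (2 and 9), and camera adjusted p = 2.06e-11 and 2.51e-08 rescaled (p = 0.176 and 9.79e-05 with estimated correlation). As deposited 150 genes were higher and 21 lower, after rescaling 238 and 213, and on both 138 and 21. The count was 31 without WT ground 3 and 38 without bzip28bzip60 ground 4.

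The ire1aire1b ground libraries had more AT1G29520 1.69 (1.81), GSTF4 1.53 (1.71), AT1G68230 1.5 (1.64), AT2G34590 1.5 (1.59) and ILA 0.61 (0.7) than WT, and less SMR7 -2.53 (-2.73), HEI10 -1.99 (-2.0), ARP9 -1.73 (-1.76) and MRD1 -1.72 (-1.78). With TSO2 -1.08 (-1.04), the DNA damage list had 0 higher and 2 lower of 16 (0 and 8 adjusted over the list alone), 0 and 5 rescaled (1 and 10), and camera adjusted p = 1.12e-15 and 1.02e-12 rescaled (p = 0.0385 and 4.51e-06 with estimated correlation). The protein folding list had 0 higher and 0 lower of 22 (0 and 4 adjusted over the list alone), 0 and 3 rescaled (0 and 9), and camera adjusted p = 1.16e-07 and 9.9e-11 rescaled (p = 0.914 and 0.0062 with estimated correlation). As deposited 11 genes were higher and 15 lower, after rescaling 36 and 57, and on both 11 and 15. Fits to the compared groups alone gave 6 genes as deposited.

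In flight the mutants differed from WT at a short list. AT2G34590 was higher in bzip28 2.31 (2.37), bzip60 2.55 (2.53), bzip28bzip60 2.5 (2.46) and ire1aire1b 2.47 (2.46). HEI10 was lower in bzip28 -4.32 (-4.05), bzip60 -4.08 (-3.88) and bzip28bzip60 -4.01 (-3.83), with MRD1 -3.68 (-3.31), -3.66 (-3.31) and -3.53 (-3.21), and AT1G44835 was lower in bzip28, -3.65 (-3.32). AT4G29200 was lower in bzip60 -2.86 (-2.52), bzip28bzip60 -2.85 (-2.51) and ire1aire1b -2.88 (-2.53), where AT3G01345 was lower too, -2.2 (-1.95). HEI10, MRD1, AT4G29200 and AT3G01345 were each called lower in flight in all 4 mutants on both scales. AT5G35375, listed at 0 in 3 of the 4 WT flight libraries, was higher in bzip28bzip60, 4.22 (3.83), AT5G09672 3.06 (2.86) and CYP96A5 0.94 (0.88) in bzip60, and AT2G27140 1.75 (1.68) and AT4G09950 1.69 (1.6) in ire1aire1b. As deposited 2 genes were higher and 29 lower in bzip28, 4 and 26 in bzip60, 3 and 31 in bzip28bzip60, and 13 and 20 in ire1aire1b. After rescaling the counts were 2 and 33, 7 and 41, 5 and 56, and 16 and 29. On both scales they were 2 and 25, 3 and 26, 2 and 30, and 13 and 19. Leaving out genes below a mean of 5 FPKM took the deposited counts to 14, 12, 13 and 10. Part of each list was shared. Without that filter 1 higher and 12 lower genes were called in flight in all 4 mutants as deposited, and 1 and 19 after rescaling. These cannot be assigned to any single mutation, as all mutants were held against the same WT libraries.

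Of the hypoxia list SAD6 -2.25 (-2.2) and ADH1 -1.23 (-1.24) were lower than WT in bzip28bzip60 in flight. There the list had 0 higher and 2 lower of 15 (0 and 12 adjusted over the list alone), 0 and 6 rescaled (0 and 13), and camera adjusted p = 2.48e-34 and 3.41e-29 rescaled (p = 0.00581 and 0.00166 with estimated correlation). In bzip28, bzip60 and ire1aire1b no gene of this list was called on both scales. Their deposited medians were -0.61, -0.63 and -0.47, with p = 0.0399, 0.044 and 0.13 with an estimated correlation. The rescaled medians were -0.52, -0.62 and -0.44, with p = 0.0167, 0.0132 and 0.0446 with an estimated correlation. Of the DNA damage list SMR7 was lower, at -2.03 (-1.89), -1.94 (-1.87) and -1.85 (-1.75) in bzip28, bzip28bzip60 and ire1aire1b. In bzip28 it had 0 higher and 3 lower of 16 (0 and 5 adjusted over the list alone), 0 and 3 rescaled (0 and 6), and camera adjusted p = 2.28e-18 and 3.3e-14 rescaled (p = 0.019 and 1.93e-06 with estimated correlation). In ire1aire1b it had 0 higher and 3 lower of 16 (0 and 5 adjusted over the list alone), 0 and 3 rescaled (0 and 5), and camera adjusted p = 5.36e-19 and 1.12e-13 rescaled (p = 0.0145 and 2.8e-06 with estimated correlation). The 4 mutants were each held against the same 4 WT libraries, so 1 unusual WT library moves all 4 comparisons.

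Genes that differed from WT in the same direction in all 4 mutants, on the ground and in flight, numbered 1 higher and 11 lower after rescaling, and 1 and 5 as deposited. AT2G34590 averaged 84.2 FPKM in the mutants and 24.9 in WT on the ground, and 56.1 and 9.47 in flight, all rescaled. HEI10 averaged 2.61 against 25.4 and 1.95 against 26.2, and MRD1 0.763 against 10.9 and 0.504 against 9.59. PARP2 was at 1.51 against 3.2 and 1.91 against 4.46, ARP9 at 5.63 against 15.4 and 6.73 against 15.1, and TK1a, AT2G18193, AT3G01345, AT3G58270, AT4G29200, AT5G60250 and the retrotransposon remnant SADHU3-2 were the others lower. HEI10 and MRD1 overlap in the annotation, so their reads may be shared. With the WT libraries split into 2 sets of 2, each held against 2 of the mutants, 1 higher and 6 lower genes were called in all 4 mutants and both conditions.

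Apart from bzip60 as deposited (9 genes higher and 4253 lower), the flight response itself differed between a mutant and WT at few genes. In bzip28 XTH11 did not fall as far as in WT, an interaction of 1.89 (1.92). As deposited it was at 1.58 ± 0.423 in flight and 1.55 ± 0.47 on the ground, against 1.62 ± 0.349 and 9.0 ± 3.54 in WT. After rescaling the means were 1.27 in flight and 2.53 on the ground, against 1.225 and 12.5 in WT. The genotypes thus differed on the ground rather than in flight. AT1G44835 rose in WT from 3.71 ± 1.0 to 14.8 ± 2.36, an interaction of -1.6 (-0.96). In bzip28 it was near 0 under both conditions, 0.121 ± 0.0861 on the ground and 0.256 ± 0.043 in flight. AT1G33950 -1.82 (-1.6) and CYP79F1 -1.2 (-1.06) rose less in bzip28 than in WT, where each was listed at 0 in 3 ground libraries, and AT1G33950 did so in ire1aire1b too, -1.55 (-1.4). In bzip28bzip60 LHCB1.3 rose less, from 110.3 ± 19.1 to 252 ± 62.7, -2.36 (-2.17), as did AIG1 -1.96 (-1.87) and UMAMIT14 -1.49 (-1.39), both listed at 0 in all 4 WT ground libraries. In bzip60 AT3G30768 4.36 (4.09), AT5G09672 3.28 (3.63), AT3G01319 3.16 (3.39), AT2G41082 -5.28 (-5.03), AT1G28730 -4.97 (-4.67) and AT5G09670 -4.84 (-4.23) led as deposited, and none passed after rescaling.

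By limma with Benjamini-Hochberg adjustment the interactions numbered 1 higher and 3 lower in bzip28, 9 and 4253 in bzip60, 0 and 3 in bzip28bzip60 and 0 and 1 in ire1aire1b as deposited. After rescaling they numbered 6 and 3, 4 and 5, 7 and 9, and 0 and 1, and on both scales 1 and 3, 1 and 5, 0 and 3, and 0 and 1. The 6 bzip60 genes on both scales were LHCB1.3, the invertase gene ATBETAFRUCT4, AIG1, MLP28, CYP79F1 and RTFL16, with rescaled interactions of -2.10, 1.91, -1.84, -1.37, -1.13 and -0.95. The bzip60 count fell from 4262 to 20 without bzip60 flight 4 or WT flight 1. Of the disrupted genes, bZIP28 was called after rescaling only, 1.23 (1.08) in bzip28 and 0.70 (1.02) in bzip28bzip60. So was bZIP60, 0.59 (1.23) in bzip60 and 1.14 (1.37) in bzip28bzip60. IRE1A and IRE1B had no called interaction. With a pseudocount of 0.1 the deposited bzip28, bzip28bzip60 and ire1aire1b counts fell, as given below. The protein folding list had a bzip28 interaction of 0.34 (0.22), 0 higher and 0 lower of 22 (0 and 0 adjusted over the list alone), 0 and 0 rescaled (7 and 0), and camera adjusted p = 6.97e-07 and 3.59e-11 rescaled (p = 0.80 and 0.0129 with estimated correlation). The photosynthesis list in bzip28bzip60 had 0 higher and 1 lower of 35 (0 and 24 adjusted over the list alone), 0 and 2 rescaled (0 and 21), and camera adjusted p = 6.79e-33 and 1.69e-27 rescaled (p = 0.145 and 0.0837 with estimated correlation).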

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

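Single libraries stood apart from the other 3 of their group in 43 of 453 groups of 4 values (9.5 percent), by a Dixon test. Chance gives about 1 in 20 such groups, 5 percent, if values follow a normal distribution. FPKM was tested as listed, and where the other 3 libraries were at 0 any value above 0 passed the test. Each flagged library is given with the range of the other 3 libraries, in FPKM unless named. In WT ground this was library 1 in AT3G05727 (1.92 against 0 to 0.164), AT4G22513 (0.116 against 0), AT3G16670 (0.0658 against 0), ATCG00410 (56.5 against 0) and AT3G30768 (26.3 against 0), library 3 in GSTF4 (2.19 against 1.4 to 1.49) and CYP79F1 (0.0248 against 0), library 4 in AT1G33950 (0.102 against 0). In WT flight this was library 2 in AT3G55790 (0.987 against 0), XTH11 (1.11 against 1.72 to 1.84) and IRE1B (10.6 against 8.96 to 9.03), library 4 in AT5G35375 (0.138 against 0). In bzip28 ground this was library 4 in AT4G22517 (0.84 against 0), AT4G22513 (1.39 against 0), AT4G22485 (1.57 against 0 to 0.0139), SIS (434 against 116 to 159.7) and XTH11 (2.25 against 1.22 to 1.36), library 1 in ATCG00390 (161 against 0) and AT4G04223 (0.542 against 1.74 to 1.84), library 3 in AT5G03090 (3.67 against 0 to 0.337). In bzip28 flight this was library 1 in AT3G05727 (862 against 322 to 394) and bZIP60 (34 against 37.4 to 37.8), library 3 in AT1G58320 (5.88 against 1.07 to 1.16). In bzip60 ground this was library 3 in AT3G05727 (41.6 against 0.363 to 4.34), AT3G55790 (73.8 against 4.28 to 14.7), AT4G22520 (2.25 against 0.375 to 0.59), AT5G09672 (17.5 against 2.79 to 4.64) and AT5G09670 (0.721 against 13.8 to 15.65), library 2 in HEI10 (1.64 against 1.34 to 1.39), library 4 in bZIP60 (11.3 against 14 to 14.6).

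In bzip60 flight this was library 2 in CYP96A5 (4.3 against 5.39 to 5.53). In bzip28bzip60 ground this was library 4 in log2 scale factor (0.15 against -0.47 to -0.40) and AIG1 (0.0303 against 0), library 1 in AT4G22485 (0.892 against 0.164 to 0.277), library 2 in MRD1 (0.426 against 0.146 to 0.164). In bzip28bzip60 flight this was library 3 in AT4G22485 (165 against 73.5 to 75.1), ESM1 (61.5 against 34.7 to 36.1) and LHCB1.3 (345 against 216 to 227). In ire1aire1b ground this was library 2 in AT4G22513 (0 against 0.109 to 0.112) and SMR7 (4.41 against 0.335 to 0.638). In ire1aire1b flight this was library 4 in total FPKM (1170335 against 945720 to 975178), library 3 in listed loci (24737 against 24390 to 24409) and AT2G34590 (66.2 against 76 to 77.5).

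Flight responses that differed between a mutant and WT were few apart from bzip60. For bzip28 there were 4 genes: XTH11 1.89, AT1G33950 -1.82, AT1G44835 -1.6 and CYP79F1 -1.2 on the log2 scale. For bzip60 there were 4262, led by AT3G30768 4.36, AT5G09672 3.28, AT3G01319 3.16, AT2G41082 -5.28, AT1G28730 -4.97 and AT5G09670 -4.84. For bzip28bzip60 there were 3, LHCB1.3 -2.36, AIG1 -1.96 and UMAMIT14 -1.49, and for ire1aire1b 1, AT1G33950 -1.55. The bzip60 count became 9 after rescaling, and 38 with a replicate block.

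In the next 3 patterns the lane test of the first, the swap and feedback tests of the second and the lane tests of the third were written after their values had been seen, and the others before they were run. Most genes had a higher deposited FPKM in flight. Had reads of the ribosomal RNA locus AT2G01021 taken up the FPKM of the other genes, a line fitted on the 20 ground libraries should give the flight scale factors. It gave 0.944 of the observed mean (0.833 to 1.003 over bootstrap draws), which leaves that explanation standing. Lane alone did not explain the pattern, since the median change in lanes 2 and 4 was 0.855, though on 9 flight and 11 ground libraries with 1 flight library each of WT, bzip60 and bzip28bzip60. More messenger RNA per seedling in flight could not be tested, with 0 added RNAs of known amount in the table.

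The bZIP28 transcript was higher than WT in libraries labelled bzip28, where the lowest library was 3.44 times (4.03 rescaled) the highest of any other genotype in flight and 0.79 times (1.59) on the ground. A swap with the other mutants was excluded by the genes mutated there, bZIP60 and IRE1A, which in each bzip28 library were at least 1.85 times (1.87 rescaled) their highest value in those mutants in flight and 1.76 times (3.98) on the ground. A swap with WT was excluded in flight, where WT was not out of place, with bZIP28 within 1.05 times (1.06 rescaled) of bzip60 and ire1aire1b, and on the ground, where that was 1.33 (1.17) and did not decide, by the genes called against WT in the 3 other mutants in flight, since for 57.1 percent of these (65.4) all ground bzip28 libraries lay beyond all ground WT libraries in the same direction and for 0 in the opposite one (80 and 38.5 percent, and 0, with flight and ground exchanged). Feedback from loss of bZIP28 that does not need bZIP60 should also raise the transcript in bzip28bzip60. There bZIP28 was at -2.64 on the ground and -1.94 in flight. That speaks against such feedback only if the bZIP28 gene is in the same state in both lines. An allele that itself removes the transcript could not show it, so feedback was not excluded. Transcription of part of the gene from inserted DNA was left open, with 0 values per exon in the table. The bzip28bzip60 line is labelled with the same bzip28-2 allele. Its bZIP28 was at 4.91 to 5.60 FPKM in flight, against 87.4 to 129 in bzip28. An insertion shared by both lines does not alone account for that difference. Swaps were tested only between groups of this series, so whether each seed line carries the allele on its label was not tested.

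After rescaling 12 genes differed from WT in the same direction in all 4 mutants and both conditions. In 20 simulated draws of unchanged genes with the shared WT libraries the highest number was 0. No gene differed in those draws and library noise was independent, so almost no gene could be called. With the WT libraries split between the mutants, 1 higher and 6 lower genes were called. The draws alone could not exclude chance through shared controls for the 12 genes. Lane was excluded for 10 of them, which stayed called in all 8 comparisons with lane as a covariate, at no less than 0.94 of their change. It was left open for AT3G58270 and PARP2, which kept at least 0.96 of their change but lost a call as the standard error grew (-0.615 ± 0.128 to -0.596 ± 0.144 and -0.478 ± 0.132 to -0.458 ± 0.137, with 0 of the 2 called in all 8). A stretch of chromosome that differs between the WT seed stock and the mutants could not be told, since 16.7 percent of the genes (2 of 12, HEI10 and MRD1) lay within 20 genes of another and 91 of 1000 random sets had as many.

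Regrouping the libraries tested whether chance could give each count. Brackets hold the number of groupings, the real one included, with as many calls, then the highest count of any other grouping, out of 35 where no number is given. As deposited the real flight counts were WT 15526 (1, 11790), bzip28 16138 (1, 15100), bzip60 9320 (1, 3161), bzip28bzip60 14161 (1, 14101) and ire1aire1b 15884 (1, 12389), and over 100 draws for the mean 17292 (1, 10527). For mutants against WT on the ground they were bzip28 135 (5, 5551), bzip60 13443 (1, 1617), bzip28bzip60 171 (1, 13) and ire1aire1b 26 (1, 18), and in flight bzip28 31 (1, 1), bzip60 30 (1, 1), bzip28bzip60 34 (1, 1) and ire1aire1b 33 (1, 1). For the interactions, over 100 draws, they were bzip28 4 (6, 2354), bzip60 4262 (1, 19), bzip28bzip60 3 (3, 17) and ire1aire1b 1 (14, 24).

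After rescaling the real flight counts were WT 11590 (1, 4116), bzip28 11390 (1, 3047), bzip60 10736 (1, 2926), bzip28bzip60 10572 (1, 867) and ire1aire1b 11143 (1, 5044), and over 100 draws for the mean 15366 (1, 1). For mutants against WT on the ground they were bzip28 641 (1, 484), bzip60 886 (1, 539), bzip28bzip60 451 (1, 200) and ire1aire1b 93 (6, 327), and in flight bzip28 35 (1, 1), bzip60 48 (1, 2), bzip28bzip60 61 (1, 1) and ire1aire1b 45 (1, 1). For the interactions, over 100 draws, they were bzip28 9 (4, 172), bzip60 9 (4, 40), bzip28bzip60 16 (4, 33) and ire1aire1b 1 (25, 26). Chance was therefore not excluded for bzip28 against WT on the ground (5 of 35) and the bzip28 and ire1aire1b interactions (6 and 14 of 100) as deposited, nor for ire1aire1b against WT on the ground (6 of 35) and its interaction (25 of 100) after rescaling. For the rest fewer groupings had as many calls, 1 of 35 or at most 4 of 100. No lower share than 1 of 35 was possible and no adjustment was made over the comparisons, so chance was not excluded by rank alone. For bzip28bzip60 flight against ground another grouping gave 14101 beside 14161 as deposited. Other groupings with several times the real count, such as 5551 beside 135 and 2354 beside 4 as deposited or 327 beside 93 and 172 beside 9 after rescaling, show that the libraries also differ in ways other than their labels, and the reason was not tested.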

How the results depend on the processing

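Alternatives that moved a count by more than 1.5 times are given here, and the cause was not tested. Main counts as deposited were 15526 for WT, 16138, 9320, 14161 and 15884 for the mutants in flight against ground, 135, 13443, 171 and 26 against WT on the ground, 31, 30, 34 and 33 in flight, and 4, 4262, 3 and 1 for the interactions, in the order bzip28, bzip60, bzip28bzip60, ire1aire1b. A pseudocount of 0.1 gave bzip28 212 and bzip28bzip60 290 against WT on the ground, bzip60 15, bzip28bzip60 17 and ire1aire1b 18 against WT in flight, bzip28 1, bzip28bzip60 1 and ire1aire1b 0 for the interaction. No filter gave ire1aire1b 40 against WT on the ground, bzip28 61, bzip60 61, bzip28bzip60 62 and ire1aire1b 60 against WT in flight, bzip28 8, bzip60 1255, bzip28bzip60 7 and ire1aire1b 7 for the interaction. A filter at a mean of 5 FPKM gave bzip28 81 and ire1aire1b 15 against WT on the ground, bzip28 14, bzip60 12, bzip28bzip60 13 and ire1aire1b 10 against WT in flight, bzip28 1, bzip28bzip60 1 and ire1aire1b 0 for the interaction. Rescaling gave bzip28 641, bzip60 886, bzip28bzip60 451 and ire1aire1b 93 against WT on the ground, bzip60 48 and bzip28bzip60 61 against WT in flight, bzip28 9, bzip60 9 and bzip28bzip60 16 for the interaction. Lane as a covariate gave bzip28 237 and bzip28bzip60 86 against WT on the ground, bzip60 1123 for the interaction. Lanes 2 and 4 alone gave bzip60 3036 flight against ground, bzip28 3357, bzip28bzip60 17 and ire1aire1b 15 against WT on the ground, bzip28 12, bzip60 11, bzip28bzip60 9 and ire1aire1b 13 against WT in flight, bzip60 10 and ire1aire1b 6 for the interaction. The library letter as a covariate gave bzip28bzip60 286 against WT on the ground, bzip60 6566 for the interaction. A replicate block gave bzip60 38 for the interaction. A fit to the compared groups alone gave bzip28 12, bzip28bzip60 10 and ire1aire1b 6 against WT on the ground, bzip28 2 and bzip60 9880 for the interaction. Omitting the 2 ground libraries with the lowest scale factors gave bzip28 88 and bzip28bzip60 585 against WT on the ground, bzip60 10030 and bzip28bzip60 11 for the interaction. In lanes 2 and 4 WT keeps only flight library 4, bzip60 only flight library 4 and bzip28bzip60 only flight library 2, so every count there against WT in flight and every interaction rests on 1 WT flight library. The list tests fell from 71 of 180 called in flight to 0 with an estimated correlation, and to 13 with both rescaling and an estimated correlation. With the rescaled values and the preset correlation 73 were called.

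Of rescaled values the main counts were 11590, 11390, 10736, 10572 and 11143 in flight against ground, 641, 886, 451 and 93 against WT on the ground, 35, 48, 61 and 45 in flight, and 9, 9, 16 and 1 for the interactions. These alternatives were added after the data were examined. A pseudocount of 0.1 gave bzip28 4 and ire1aire1b 0 for the interaction. No filter gave ire1aire1b 148 against WT on the ground, bzip60 15 and ire1aire1b 4 for the interaction. A filter at a mean of 5 FPKM gave ire1aire1b 46 against WT on the ground, bzip28 22, bzip60 24, bzip28bzip60 37 and ire1aire1b 23 against WT in flight, bzip28 2 and ire1aire1b 0 for the interaction. Lane as a covariate gave bzip28 14 and bzip60 20 for the interaction. Lanes 2 and 4 alone gave WT 7125, bzip60 5032 and bzip28bzip60 5000 flight against ground, bzip28 267, bzip60 57, bzip28bzip60 46 and ire1aire1b 36 against WT on the ground, bzip28 12, bzip60 12, bzip28bzip60 11 and ire1aire1b 13 against WT in flight, bzip28 4, bzip28bzip60 4 and ire1aire1b 5 for the interaction. The library letter as a covariate gave ire1aire1b 2 for the interaction. A replicate block gave ire1aire1b 0 for the interaction. A fit to the compared groups alone gave bzip28 60, bzip60 29, bzip28bzip60 29 and ire1aire1b 13 against WT on the ground, bzip28 23 against WT in flight, bzip28 1, bzip60 5 and ire1aire1b 2 for the interaction. Omitting the 2 ground libraries with the lowest scale factors gave bzip28 18, bzip60 14 and bzip28bzip60 30 for the interaction. The limit on lanes 2 and 4 holds here too.

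Omitting single libraries moved these deposited counts, given as lowest to highest. bzip28 against WT on the ground: 59 to 531 against 135, moved by omitting bzip28 ground 1 (59), bzip28 ground 2 (72), bzip28 ground 3 (220), bzip28 ground 4 (531), WT ground 1 (69), WT ground 2 (287), WT ground 3 (68) and WT ground 4 (71). bzip28bzip60 against WT on the ground: 31 to 160 against 171, moved by omitting bzip28bzip60 ground 1 (81), bzip28bzip60 ground 4 (38), WT ground 1 (104), WT ground 2 (105), WT ground 3 (31) and WT ground 4 (99). bzip60 against WT in flight: 16 to 28 against 30, moved by omitting bzip60 flight 1 (18), bzip60 flight 3 (18), bzip60 flight 4 (19) and WT flight 2 (16). bzip28bzip60 against WT in flight: 21 to 44 against 34, moved by omitting bzip28bzip60 flight 1 (21), bzip28bzip60 flight 4 (21) and WT flight 2 (22). bzip60 interaction: 20 to 7613 against 4262, moved by omitting bzip60 flight 2 (440), bzip60 flight 3 (434), bzip60 flight 4 (20), bzip60 ground 1 (43), bzip60 ground 2 (50), bzip60 ground 4 (7024), WT flight 1 (20), WT flight 2 (30), WT flight 3 (7613), WT flight 4 (149), WT ground 2 (137) and WT ground 4 (192). bzip28bzip60 interaction: 3 to 6 against 3, moved by omitting bzip28bzip60 flight 3 (6), bzip28bzip60 ground 3 (5) and WT flight 4 (5). ire1aire1b interaction: 1 to 2 against 1, moved by omitting ire1aire1b flight 3 (2) and WT flight 3 (2).

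The same for rescaled values. bzip28 against WT on the ground: 391 to 853 against 641, moved by omitting WT ground 4 (391). bzip60 against WT on the ground: 437 to 1101 against 886, moved by omitting bzip60 ground 2 (507), WT ground 3 (437) and WT ground 4 (528). bzip28bzip60 against WT on the ground: 180 to 616 against 451, moved by omitting bzip28bzip60 ground 1 (241) and WT ground 3 (180). ire1aire1b against WT on the ground: 43 to 183 against 93, moved by omitting ire1aire1b ground 1 (47), ire1aire1b ground 4 (183) and WT ground 4 (43). bzip60 against WT in flight: 26 to 57 against 48, moved by omitting bzip60 flight 1 (26), bzip60 flight 3 (30), bzip60 flight 4 (30) and WT flight 3 (31). bzip28bzip60 against WT in flight: 37 to 63 against 61, moved by omitting bzip28bzip60 flight 2 (37) and WT flight 3 (38). bzip28 interaction: 6 to 31 against 9, moved by omitting bzip28 ground 1 (15), bzip28 ground 2 (16), bzip28 ground 3 (15) and WT ground 2 (31). bzip60 interaction: 6 to 27 against 9, moved by omitting bzip60 ground 4 (24), WT ground 1 (25) and WT ground 2 (27). bzip28bzip60 interaction: 7 to 40 against 16, moved by omitting bzip28bzip60 flight 1 (7), bzip28bzip60 ground 1 (7), WT flight 2 (9), WT flight 3 (8), WT flight 4 (9), WT ground 2 (40), WT ground 3 (7) and WT ground 4 (10). ire1aire1b interaction: 1 to 3 against 1, moved by omitting ire1aire1b flight 3 (3), ire1aire1b ground 2 (2) and ire1aire1b ground 4 (2).

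Some named genes changed direction and were called on at least 1 of the 2 settings, and those called on neither are left out here. Under rescaling these were, in WT flight against ground, bZIP28 -0.76, IRE1A -0.64 and IRE1B -0.17, in bzip28 IRE1A -0.61 and IRE1B -0.15, in bzip28bzip60 IRE1A -0.54, in ire1aire1b bZIP28 -0.63 and IRE1A -0.29, and in the mean bZIP28 -0.27, bZIP60 -0.69, IRE1A -0.52 and IRE1B -0.029. For bzip60 against WT on the ground they were bZIP28 -0.22, IRE1A -0.104 and IRE1B -0.099. That bZIP28 difference, 0.39 as deposited, also lost its call with a pseudocount of 0.1 (0.41), with no filter (0.39) and with lane as a covariate (0.35), and ran from 0.33 to 0.47 over single omissions. In lanes 2 and 4 alone AT1G28730 in the bzip60 interaction and ATMG00190 in WT flight went to 0, and ATMG01390 in bzip60 flight to 0.07. Of 830 named values 794 kept their label under rescaling, 792 with lane as a covariate, 687 in lanes 2 and 4 and 817 with a replicate block. List members entered these checks only where called in the same direction on both scales, which fixed their label under rescaling. Members that lost their call, such as BAG7 in WT flight, are not counted here. Of the 180 flight list tests none was called by camera in the opposite direction.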

Other observations

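A separate list asked whether the starvation genes lower in flight are part of a wider fall in genes of breakdown. It held 16 genes of autophagy and amino acid breakdown, chosen before they were looked at, and its bounds were set beforehand. After rescaling AT1G21400 was at -2.15, PPDK at -1.83 and ETFQO at -0.96 in the mean of the 5 genotypes, and 12 of 15 measured genes were lower and 0 higher (camera p = 2.66e-05, or p = 0.0191 with estimated correlation). As deposited 9 were higher and 3 lower. The rescaled median of -0.436 fell between the 2 bounds, so it could not be told whether ground seedlings were shorter of carbon than flight seedlings when fixed.

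Lists not described above are given for the mean of the 5 genotypes. Phenylpropanoid genes had 14 higher and 0 lower of 14 (14 and 0 adjusted over the list alone), 11 and 2 rescaled (11 and 2), with camera adjusted p = 0.187 and 0.201 rescaled (p = 0.802 and 0.663 with estimated correlation). DNA damage genes had 15 higher and 0 lower of 16 (15 and 0 adjusted over the list alone), 10 and 1 rescaled (10 and 1), with camera adjusted p = 0.344 and 0.201 rescaled (p = 0.802 and 0.465 with estimated correlation). Root hair genes had 11 higher and 0 lower of 12 (11 and 0 adjusted over the list alone), 9 and 1 rescaled (9 and 1), with camera adjusted p = 0.993 and 0.23 rescaled (p = 0.997 and 0.663 with estimated correlation), and other root genes 7 higher and 1 lower of 8 (7 and 1 adjusted over the list alone), 5 and 1 rescaled (5 and 1), with camera adjusted p = 0.993 and 0.398 rescaled (p = 0.997 and 0.663 with estimated correlation). Cellulose synthases had 6 higher and 0 lower of 6 (6 and 0 adjusted over the list alone), 3 and 0 rescaled (3 and 0), with camera adjusted p = 0.397 and 0.548 rescaled (p = 0.802 and 0.761 with estimated correlation). Touch genes had 6 higher and 0 lower of 7 (6 and 0 adjusted over the list alone), 3 and 2 rescaled (3 and 2), with camera adjusted p = 0.993 and 0.848 rescaled (p = 0.997 and 0.917 with estimated correlation). Iron genes had 2 higher and 2 lower of 7 (2 and 2 adjusted over the list alone), 2 and 5 rescaled (2 and 5), with camera adjusted p = 0.00902 and 0.208 rescaled (p = 0.535 and 0.465 with estimated correlation), and phosphate genes 2 higher and 1 lower of 4 (2 and 1 adjusted over the list alone), 1 and 3 rescaled (1 and 3), with camera adjusted p = 0.193 and 0.305 rescaled (p = 0.753 and 0.527 with estimated correlation). Of the seed storage list 1 gene was measured, OLEO3, with 1 higher and 0 lower of 1 (1 and 0 adjusted over the list alone), 1 and 0 rescaled (1 and 0), with camera adjusted p = 0.347 and 0.229 rescaled (p = 0.753 and 0.465 with estimated correlation).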
